A study of Mus musculus with 12 samples.

How the data were processed

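Gene expression was measured in a conditionally immortalized mouse podocyte line, a cultured form of the epithelial cells that cover the kidney's filtering capillaries. Per the labels' protocols, the line carries a temperature-sensitive T antigen, grows at 33 °C with γ-interferon, and was differentiated at 37 °C and used on day 14. Fluid flow shear stress of 2 dynes per square centimetre, a flow of 75 ml per minute, was applied for 2 h. Control cells were kept in the same hood and incubator without shear, and no harvest time is recorded for them here. Sheared cells were harvested at the end of shear (End), and 2 h and 24 h after it (Post-2hr and Post-24hr). Each of the 4 groups holds 3 arrays, numbered 1 to 3 in the labels. The labels do not say that the 3 samples of a group came from separate cultures, so a p-value here measures the spread between these samples, which may be technical.

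RNA was hybridised to Affymetrix Mouse Exon 1.0 ST arrays, and probes on different exons were summarised into 1 value per gene, per the labels' protocols. The deposited values are on the log2 scale, and the submitters' processing notes name RMA (background correction, quantile normalization and probe summary) and Partek, without versions. The order and settings of these steps are not given in the sources used here. RMA forces arrays towards a common distribution, so a change of total RNA output per cell would not be seen. The table holds 23332 rows for 12 arrays with 0 missing values, from 1.63 to 14.23. Array medians ran from 6.928 to 7.115. No detection calls or scanner files were used here, so it is not known which dim rows lie above background. For arrays, their number limits the precision.

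Rows were named through a platform annotation table. Of the rows, 14996 have 1 gene symbol, 1019 have several and 7317 are unnamed here. Of the rows with 1 symbol, 14941 have a gene identifier that is also in a RefSeq gene table (assembly GRCm38.p6), and the update changed 0 symbols. No gene was named from a row with several symbols. The genome build behind the values is not given in the sources used here, so no coordinates are printed. Gene list tests used 1 row per gene, the brightest on average over the arrays, for 14860 genes (135 symbols have more than 1 row).

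All 12 arrays entered 1 linear model per row with a mean for each group (limma 3.58.1, R 4.3.3, lmFit and eBayes), which left 8 residual degrees of freedom and added 2.16 prior degrees of freedom. The 3 main comparisons were each harvest after shear against Control. The 2 secondary comparisons were Post-2hr minus End and Post-24hr minus Post-2hr. A moderated F test asked for any difference among the groups. All rows were tested, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Changes are differences of mean log2 values, first group minus second, with the model's standard error (SE). Of 29 gene lists, 28 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 84 tests of the main comparisons. The list of small nucleolar RNAs had 0 measured members. The same tests in the secondary comparisons, 56 in all, were added after the data were seen. Within a list, members were also counted with p-values adjusted over the list alone.

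The design, the lists and the rule for named genes were fixed before the data were examined. For each main comparison the rule took up to 8 genes with the largest rise and 8 with the largest fall among rows with 1 symbol that passed the threshold and whose groups did not overlap, leaving out predicted gene models. It took up to 5 of each for a secondary comparison. Where no gene passed it took the 5 with the smallest p, and it added up to 2 risen and 2 fallen members past the threshold for each list. Ptgs2, Ptger2, Ptger4, Ptges, Nphs1, Wt1, Synpo, Podxl, Axin2 and Ctnnb1 were always named where measured. Synpo has no value because no row with 1 symbol named it, and a further gene of this rule is not reported here. Other list members were chosen as examples after their values were seen.

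The replicate 1 arrays of all groups lay apart from the others. The labels give no scan date or batch. A fit with replicate 1 set apart from replicates 2 and 3 as a fixed term with 2 levels (called here the set-apart fit), a fit on replicates 2 and 3 only, and changes within each set were therefore added after the data were seen. The alternatives chosen before that were replicate number as a block, median centring, quantile normalization, filters at the 25th and 50th percentiles of mean level, rows with 1 symbol only, an intensity trend in the variance, an ordinary linear model without variance moderation, array weights, each of the 12 arrays left out, only the groups compared, a correlation estimated for each list, limma's directional fry test, and the mean of a gene's rows. The methods were tested on simulated data for Post-2hr minus Control with 23332 rows. Of 100 rows changed by 1 on the log2 scale, 60% were recovered, and of 100 changed by 2, 93%, with 8 false calls. With the spread left after replicate 1 was set apart, these shares were 76% and 93%, with 6 false calls. In both simulations rows were drawn independently. The first treated the replicate 1 difference as random spread and held no shared replicate 1 term, unlike the arrays. Its shares and false calls therefore need not hold for the main fit. For End minus Control, a list shifted by 0.5 over 14860 genes had an adjusted p = 3.27e-12, and 0 other lists passed. In that list simulation genes were drawn independently and without a replicate 1 difference. It therefore does not show how often lists pass by chance when their members move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.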

Results

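Podocytes were exposed to fluid flow shear stress for 2 h and profiled on 12 exon arrays, 3 for each of 4 groups: unsheared controls, the end of shear, and 2 h and 24 h of recovery. The comparisons ask which transcripts differed from the controls at each harvest, and which differed between successive harvests. Values are RMA-normalized log2 expression, and array medians lay between 6.928 and 7.115.

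The largest contrast among the arrays did not follow the shear groups. The first principal component held 42.41% of the variance and separated the replicate 1 array of every group (−53.24 to −26.73) from the replicate 2 and 3 arrays (3.00 to 34.50). With group means held in the fit, 7112 of 23332 rows (30.5%) differed between replicate 1 and the others, 4557 higher and 2555 lower in replicate 1 (limma, Benjamini-Hochberg). Genes of the G2 and M phases of the cell cycle were lower in replicate 1 by a median of −1.47 on the log2 scale, and 17 of the 18 measured members passed as lower. That list had an adjusted p = 5.47e-08 with the preset correlation and an adjusted p = 0.35 with an estimated correlation. Results are therefore also given with replicate 1 set apart, and as changes within replicate 1 and within replicates 2 and 3.

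**Figure D1:**
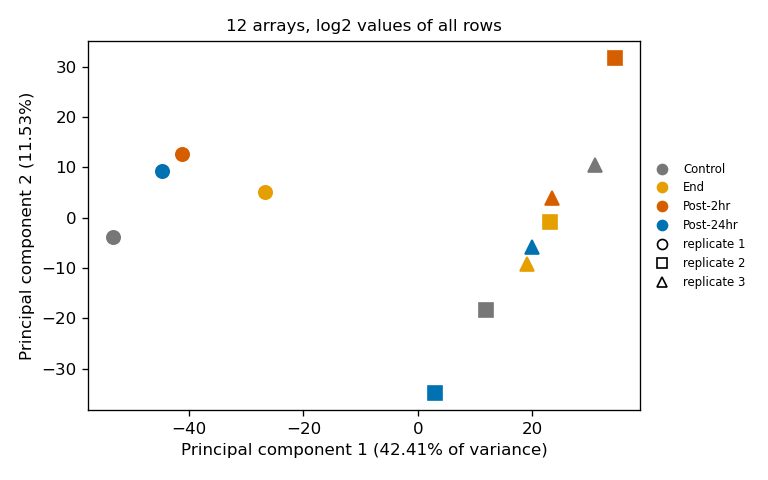
Each point is 1 array, placed by its first (x axis) and second (y axis) principal component score over the log2 values of all rows; colour gives the group and shape the replicate number. The 4 replicate 1 arrays lie between −53.24 and −26.73 on the first component and the others between 3.00 and 34.50.

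At the end of shear, immediate early transcription factors, the genes that many stimuli induce within minutes, were higher than in the controls as a group. Of 24 measured members, 23 had higher means, with a median change of 0.50 (camera adjusted p = 2.61e-15; adjusted p = 0.0688 with an estimated correlation). Adjusted over the list alone, 10 rose and 0 fell (13 and 0 with replicate 1 set apart); over all rows, 0 passed. The 10 were Fos, Fosl1, Junb, Egr1, Egr2, Egr3, Ier2, Ier5, Btg2 and Klf10. Fos, a subunit of the AP-1 transcription factor, went from 7.28 ± 1.10 to 9.64 ± 0.19 (SD, n = 3), a difference of 2.37 ± 0.62 (SE). Egr2 differed by 2.24 ± 0.63 and Junb, another AP-1 subunit, by 1.61 ± 0.23. The list's median change was 0.70 in replicate 1 and 0.47 in replicates 2 and 3.

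Of the other lists at End, MAPK feedback regulators, many of which dampen the kinase cascade that induces them, had a median change of 0.28 (adjusted p = 0.00237). Adjusted over the list alone, Dusp2, a MAP kinase phosphatase, rose by 1.11 and Ier3 by 1.04, and 0 fell (5 rose and 0 fell with replicate 1 set apart); over all rows 0 passed. Sterol and fatty acid synthesis genes had a median of 0.14, with 17 of 18 means higher (adjusted p = 0.00214), and Insig1, a feedback regulator of the pathway, differed by 0.51 ± 0.22. Genes described as shear-responsive in endothelium (median 0.20) and inflammatory cytokines and NF-kB targets (median 0.10) each had an adjusted p = 0.0426. Interferon response genes were lower by a median of −0.14, in 14 of 17 members (adjusted p = 0.00787), with a median of 0.05 in replicate 1 and −0.21 in replicates 2 and 3; Cxcl10 had a difference of the other sign (1.04 ± 0.59). Adjusted over the list alone, 0 members of these 4 lists passed; with replicate 1 set apart 5 shear and 3 sterol genes rose, and 0 inflammatory or interferon genes passed. With an estimated correlation none of these 5 lists passed (adjusted p = 0.464 for MAPK feedback, 0.757 for sterol synthesis, 0.73 for the shear list, 0.846 for inflammatory genes and 0.814 for interferon response).

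No single row passed at End over all rows (0 of 23332, limma, lowest adjusted p = 0.425), and the ordinary linear model without variance moderation also called 0. In the main fit 845 rows had an unadjusted p under 0.05, where evenly spread p-values would give 1167. That fit counts the replicate 1 difference as spread within groups, so 1167 is not its chance count. The 5 named genes with the smallest p, none of which passed, were Junb, Ier3 (1.04 ± 0.16), Zbed5 (0.96 ± 0.15), Bmf, a BH3-only protein that promotes apoptosis (1.04 ± 0.20), and Krtap4-7 (−0.88 ± 0.16). Their adjusted p ran from 0.425 to 0.688. With replicate 1 set apart 0 rows passed, and 1675 had an unadjusted p under 0.05, beside the same 1167 for evenly spread p-values. In the fits that left out 1 array, the MAPK feedback list lost its call without Control replicate 1 (adjusted p = 0.18), as it did on replicates 2 and 3 only (adjusted p = 0.0698), and the sterol list without Control replicate 1 or End replicate 3 (adjusted p up to 0.171). The shear and the inflammatory lists lost theirs without Control replicate 1, End replicate 2 or 3, or Post-2hr replicate 2 (adjusted p up to 0.529 and 0.942), and the shear list also after quantile normalization. The interferon list lost its call without Control replicate 2 or 3 or End replicate 1 (adjusted p up to 0.279), and its median was above 0, at 0.09, without Control replicate 3. Other medians moved by over 1.5 times without 1 array: MAPK feedback to 0.075 (Control replicate 1) and 0.157 (End replicate 2), sterol to 0.235 (End replicate 1) and 0.075 (End replicate 3), and shear genes to 0.028 (Control replicate 1). The interferon median moved to −0.307 (Control replicate 1), −0.252 (End replicate 3) and −0.025 (End replicate 1), and the inflammatory median to 0.011, 0.168 and 0.215 without Control replicates 1, 2 and 3 and to 0.239 without End replicate 1.

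At 2 h of recovery, the only harvest at which single genes passed against the controls over all rows, 3 rose and 1 fell. Plaur, the receptor of urokinase plasminogen activator, rose from 8.36 ± 0.13 to 9.90 ± 0.03 (SD, n = 3), a change of 1.54 ± 0.10 (SE) or 2.90-fold (adjusted p = 0.00079). Fosl1, an AP-1 subunit, rose by 1.68 ± 0.18 or 3.20-fold (adjusted p = 0.0182), and Klf5, a zinc finger transcription factor, by 0.88 ± 0.09 or 1.84-fold (adjusted p = 0.0149). Gpr146, a G protein-coupled receptor, changed by −0.90 ± 0.11, or 1.86-fold lower (adjusted p = 0.0371). The naming rule asks for groups that do not overlap, so the changes of the 4 genes must have the same sign in both sets of arrays. For Plaur they were 1.43 in replicate 1 and 1.59 in replicates 2 and 3.

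**Figure D2:**
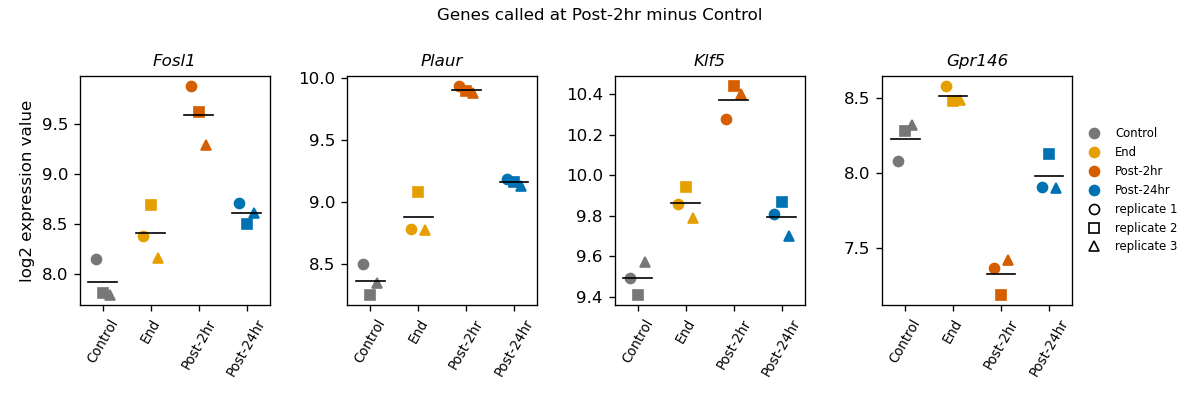
Each panel shows 1 gene that passed at Post-2hr minus Control; points are the log2 values (y axis) of single arrays, colour gives the group (x axis), shape the replicate number, and bars the means of 3 arrays. The 3 Post-2hr values of Plaur, with a mean of 9.90, lie above all others, and those of Gpr146, with a mean of 7.33, lie below all others.

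With replicate 1 set apart, a fit chosen after the data were seen, 36 rows passed at Post-2hr (24 higher and 12 lower), including the 4. Among the largest rises in that fit were Nr4a1, an orphan nuclear receptor of the immediate early class (2.38, set-apart adjusted p = 0.0417), and the chemokines Ccl7 (2.04, 0.0306 as adjusted p) and Cxcl1 (1.76, adjusted p = 0.0417). Tcim differed by 1.75 (adjusted p = 0.0342), the cytokine Lif by 1.32 (adjusted p = 0.0417) and Hk2, a hexokinase, by 1.22 (adjusted p = 0.0294). Among rows with 1 symbol, predicted gene models left out, the largest falls after Gpr146 were Sesn1, a stress-inducible sestrin (−0.88, adjusted p = 0.0404), Cox7b, a subunit of cytochrome c oxidase (−0.75, adjusted p = 0.0306), Atf7ip (−0.60, adjusted p = 0.0422), Acvr1b, an activin receptor (−0.56, adjusted p = 0.0328), and C1rl (−0.51, adjusted p = 0.0316). Without that term these 11 genes had adjusted p from 0.166 for Tcim to 0.638 for Cox7b. With replicate number as a block with 3 levels, Sesn1 (adjusted p = 0.0502) and Atf7ip (adjusted p = 0.0712) did not pass. On replicates 2 and 3 only, 0 rows passed in limma, and 2652 had an unadjusted p under 0.05; 0 rows also passed in a fit of only the 2 groups compared. The Plaur call held in all 12 fits that left out 1 array. Klf5 lost its call without Control replicate 2 or 3, End replicate 1, or Post-2hr replicate 2 or 3 (adjusted p up to 0.134), and Fosl1 without Control replicate 2 or 3, End replicate 1, Post-2hr replicate 1 or 2, or Post-24hr replicate 3 (up to 0.165). Gpr146 kept its call only without Control replicate 1 or Post-24hr replicate 2, and reached an adjusted p = 0.281 otherwise; its call was also lost after median centring or quantile normalization. Fosl1 and Gpr146 did not pass without variance moderation.

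As groups, 3 sets of signalling genes were higher at Post-2hr. Immediate early factors had a median change of 0.67, with 23 of 24 means higher (camera adjusted p = 2.69e-15; adjusted p = 0.0688 with an estimated correlation). Adjusted over the list alone 8 rose (Fosl1, Fosl2, Junb, Egr3, Nr4a1, Nr4a2, Klf10 and Maff) and 0 fell (16 and 0 with replicate 1 set apart), against 1, Fosl1, over all rows. All 16 MAPK feedback regulators had higher means, with a median of 0.55 (adjusted p = 5.65e-12; adjusted p = 0.0688 with an estimated correlation). Of these, 6 rose adjusted over the list alone and 0 over all rows: Dusp4 (1.15), Ier3 (1.15), Spry4 (0.90), Spred2 (0.74), Dusp10 (0.64) and Errfi1 (0.61). Setting replicate 1 apart made that 9. Inflammatory cytokines and NF-kB targets had a median of 0.39, with 23 of 25 means higher (adjusted p = 1.12e-10; adjusted p = 0.299 with an estimated correlation), and 5 rose adjusted over the list alone (Ccl7, Cxcl1, Tnfaip3, Lif and Nfkbiz; 9 with replicate 1 set apart) against 0 over all rows. Tnfaip3, an inhibitor of NF-kB signalling, differed by 1.40 ± 0.31. The inflammatory median was 0.222 without Post-2hr replicate 3, and the list still passed.

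Genes described as shear-responsive in endothelium had a median of 0.28 at Post-2hr (adjusted p = 0.000133; adjusted p = 0.278 with an estimated correlation), and Tgfb1 (0.50) and Cyp1b1 (0.48) rose adjusted over the list alone (8 rose and 1 fell with replicate 1 set apart). The cAMP and CREB targets had a median of 0.25 (adjusted p = 0.0112; adjusted p = 0.464 with an estimated correlation); Nr4a1 and Nr4a2 rose and Ppargc1a, a coactivator of mitochondrial genes, fell by 0.89, adjusted over the list alone (4 rose and 1 fell with replicate 1 set apart). Nr4a1 and Nr4a2 are also in the immediate early list. Macrophage and leukocyte markers had a median of 0.23, with 11 of 12 means higher (adjusted p = 0.00736; adjusted p = 0.361 with an estimated correlation), of 0.06 in replicate 1 and 0.28 in replicates 2 and 3. No member passed adjusted over the list alone. Ptprc, the common leukocyte antigen, was at 3.99 ± 0.09 against 3.97 ± 0.09 (SD, n = 3). Marker rows were mostly dim. The median level per array was 5.04 to 5.67 for the macrophage list and 5.57 to 5.80 for endothelial markers. The lower quartile of all rows was 5.216 to 5.310. YAP and TAZ targets (median 0.06), NRF2 and oxidative stress genes (0.14) and endothelial markers (0.08) each had an adjusted p = 0.0426, and each had an adjusted p = 0.757 with an estimated correlation. Of these 3 lists, Srxn1 alone rose adjusted over the list alone (0.80 ± 0.21); with replicate 1 set apart 4 NRF2 genes and 1 YAP and TAZ target rose. The YAP and TAZ and the NRF2 lists lost their calls after median centring or quantile normalization, and the endothelial list after quantile normalization. In the fits that left out 1 array, the YAP and TAZ list lost its call without Control replicate 1 or 3 or Post-2hr replicate 2 or 3 (adjusted p up to 0.418), and the NRF2 list without Control replicate 2 or 3 or Post-2hr replicate 1 (up to 0.434). The endothelial list lost its call without Control replicate 1 or 2 or Post-2hr replicate 2 (up to 0.361) and on replicates 2 and 3 only, and the cAMP list without Control replicate 1 or 3 (up to 0.0976). Without 1 array, medians moved by over 1.5 times for macrophage markers, to 0.135 (Control replicate 3) and 0.113 (Post-2hr replicate 2), for cAMP targets, to 0.134 (Control replicate 1), and for endothelial markers, to 0.148 (Control replicate 3) and 0.029 (Post-2hr replicate 2). The YAP and TAZ median ran up to 0.258, moving without each Control and each Post-2hr array, and the NRF2 median from 0.049 to 0.337, moving without Control replicate 1 or 3 and each Post-2hr array. With replicate 1 set apart and the correlation estimated, 4 lists passed at Post-2hr (immediate early, MAPK feedback, shear and inflammatory genes, each with adjusted p = 0.0483). The shear list is not separate from the others. It shares Klf2 and Klf4 with the immediate early list, and Ccl2, Icam1 and Vcam1 with the inflammatory list.

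At 24 h of recovery, no single row passed (0 of 23332, limma; lowest adjusted p = 0.372), 561 rows had an unadjusted p under 0.05, and the ordinary linear model without variance moderation also called 0. The 5 named genes with the smallest p, none of which passed, were Plaur (0.80 ± 0.10), Plk2, a polo-like kinase (0.62 ± 0.10), Vmn1r82 (1.09 ± 0.20), Olfr432 (0.70 ± 0.15) and Prr15 (−0.64 ± 0.14). The vomeronasal receptor Vmn1r82 and the olfactory receptor Olfr432 were dim, with control means of 3.22 and 3.90. With replicate 1 set apart 0 rows passed, and 1197 had an unadjusted p under 0.05.

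MAPK feedback regulators and immediate early factors were still higher than in the controls at 24 h as groups. MAPK feedback genes had a median of 0.41, with 15 of 16 means higher (adjusted p = 6.49e-12; adjusted p = 0.0688 with an estimated correlation), and Spred2 (0.73) and Ier3 (0.64) rose adjusted over the list alone (9 with replicate 1 set apart); the median was 0.256 without Control replicate 1, and the list still passed. The immediate early list had a median of 0.43, with 18 of 24 means higher (adjusted p = 3.44e-08; adjusted p = 0.278 with an estimated correlation), and 0 members passed over all rows or adjusted over the list alone, against 11 risen and 0 fallen, adjusted over the list alone, with replicate 1 set apart. G2 and M phase genes had the largest median, 0.51, and all 18 means were higher (adjusted p = 6.21e-05; adjusted p = 0.757 with an estimated correlation), with 0 members past the threshold adjusted over the list alone, replicate 1 set apart or not. Top2a, a topoisomerase of dividing cells, differed by 0.48 ± 0.80 and Mki67 by 0.86 ± 0.78. Their median change was −0.30 in replicate 1 and 0.90 in replicates 2 and 3. Without Control replicate 1 the list no longer passed (median 0.166, adjusted p = 0.226), nor without Post-24hr replicate 2 (0.147, adjusted p = 0.302) or Post-24hr replicate 3 (0.2, adjusted p = 0.161); without Post-24hr replicate 1 the median was 1.237.

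**Figure D3:**
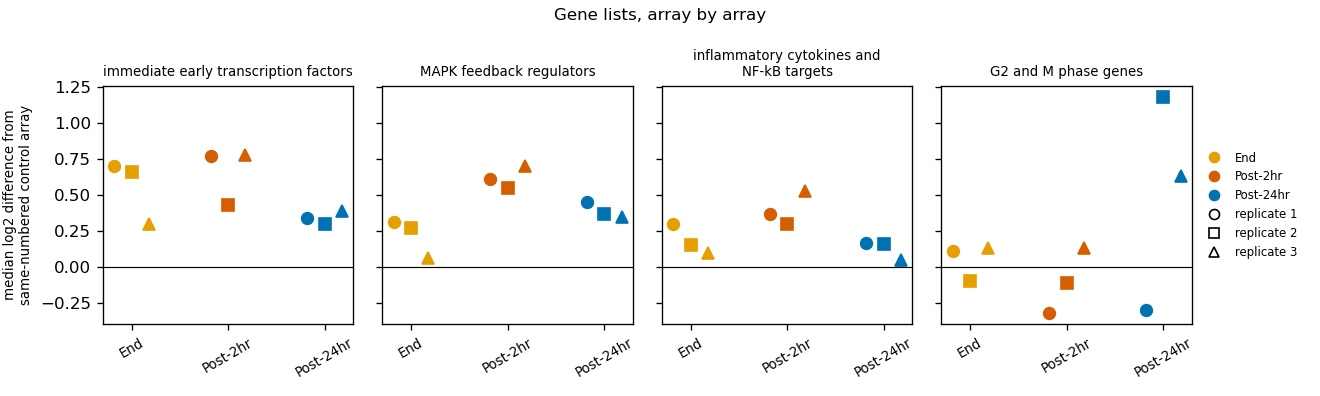
Each point is the median over a gene list's members of the log2 difference (y axis) between 1 sheared array and the control array of the same replicate number; panels are lists, colour gives the group (x axis) and shape the replicate number. The G2 and M phase genes at Post-24hr stand at −0.30 for replicate 1, 1.18 for replicate 2 and 0.63 for replicate 3.

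The actin cytoskeleton and focal adhesion list had a median of 0.15 at 24 h, with 24 of 27 means higher (adjusted p = 3.3e-05; adjusted p = 0.757 with an estimated correlation). Inflammatory genes (median 0.11, adjusted p = 0.00599), sterol synthesis genes (0.10, adjusted p = 0.00937), and YAP and TAZ targets (0.16, adjusted p = 0.0233) also passed, each with an adjusted p = 0.757 with an estimated correlation. Heat shock proteins passed with a median of 0.05 (adjusted p = 0.0233; adjusted p = 0.422 with an estimated correlation). Adjusted over the list alone, 0 members of these 5 lists passed; with replicate 1 set apart 2 actin genes and 1 inflammatory gene rose. Without Control replicate 1, none of the 5 lists passed (adjusted p = 0.666 for actin, with a median of 0.009). Without that array the inflammatory list had an adjusted p = 0.765 and the YAP and TAZ list an adjusted p = 0.565. Both lists were also lost without Post-24hr replicate 2 or 3. The sterol and heat shock lists were also lost without Control replicate 3 or Post-24hr replicate 2 or 3. The highest adjusted p was 0.798 for the sterol list, without Post-24hr replicate 3, and 0.21 for the heat shock list, without Control replicate 1. On replicates 2 and 3 only, the YAP and TAZ and the heat shock lists did not pass. Without 1 array, medians moved by over 1.5 times for actin genes, also to 0.235 (Control replicate 2), 0.245, 0.046 and 0.067 (Post-24hr replicates 1, 2 and 3), and for inflammatory genes, to −0.007, 0.212 and 0.194 (Control replicates 1, 2 and 3) and 0.271 (Post-24hr replicate 1). Sterol genes moved to 0.053 (Control replicate 1), 0.208 and 0.047 (Post-24hr replicates 1 and 3), YAP and TAZ targets to 0.025 (Control replicate 1) and 0.062 (Post-24hr replicate 2), and heat shock genes to 0.078 and 0.12 (Control replicates 1 and 2) and 0.144 (Post-24hr replicate 3).

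Between the end of shear and 2 h of recovery, 6 rows passed, 3 higher and 3 lower at Post-2hr, 5 of them with 1 gene symbol. Plaur rose by 1.02 ± 0.10 (adjusted p = 0.0196) and the dim row of Vmn1r82 by 1.62 ± 0.20, from 2.86 to 4.48 (adjusted p = 0.0456). Bmf fell by 1.67 ± 0.20 (adjusted p = 0.0456), Gpr146 by 1.19 ± 0.11 (adjusted p = 0.0107) and Runx1t1, a transcriptional corepressor, by 0.95 ± 0.12 (adjusted p = 0.0486). With replicate 1 set apart 36 rows passed (8 higher and 28 lower), which include the 6; added named genes were Fosl1 (1.19), Hk2 (1.12), Ppargc1a (−1.49), Sesn1 (−1.11) and Fbxo32, a ubiquitin ligase of muscle wasting (−1.10). With replicate number as a block with 3 levels only 6 rows passed (2 higher and 4 lower), and these 5 genes did not (adjusted p = 0.0534 for Sesn1 and 0.0545 for the others), nor did Vmn1r82 (adjusted p = 0.0545). On replicates 2 and 3 only, 0 rows passed in limma and 2888 had an unadjusted p under 0.05. None of the 5 genes held in all 12 fits that left out 1 array. Gpr146 lost its call without End replicate 1 or 3 or Post-2hr replicate 3 (adjusted p up to 0.113), and Plaur without Control replicate 3, End replicate 1 or 3, or any Post-2hr array (up to 0.167). Bmf kept its call only without Post-2hr replicate 1 or Post-24hr replicate 1 or 3 (up to 0.291 otherwise), and Vmn1r82 only without Post-24hr replicate 2 or 3 (up to 0.27 otherwise). Runx1t1 lost its call without any 1 of the 12 arrays (up to 0.334). Bmf was also lost after quantile normalization, Vmn1r82 and Runx1t1 with an intensity trend in the variance, and Vmn1r82, Bmf and Runx1t1 without variance moderation.

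Between 2 h and 24 h of recovery no row passed (0, limma; lowest adjusted p = 0.24), 1332 had an unadjusted p under 0.05, and the ordinary linear model without variance moderation also called 0. The 5 named genes with the smallest p were all lower at 24 h: Tcim (−2.02 ± 0.28), Nr4a2 (−1.31 ± 0.20), Pmepa1, a TGF-beta-induced inhibitor of that pathway (−1.17 ± 0.16), Plaur (−0.74 ± 0.10) and Klf5 (−0.58 ± 0.09). With replicate 1 set apart, 2 rows passed, the calcium-regulated transcription factor Nfatc1 (−1.03, adjusted p = 0.0402) and Ugdh (−0.86, adjusted p = 0.0402).

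Prostaglandin E2 is among the treatments the labels mention, on samples not analysed here. Ptgs2, the inducible cyclooxygenase, stood at 8.51 ± 1.22 in the controls, 10.34 ± 0.74 at End, 11.12 ± 0.59 at Post-2hr and 9.57 ± 0.86 at Post-24hr (SD, n = 3). Its differences from Control were 1.83, 2.61 and 1.06, each ± 0.64 (SE), and none passed over all rows (adjusted p = 0.536 at Post-2hr). The sets of arrays differed in size of change: 0.60, 1.92 and 0.63 in replicate 1, and 2.45, 2.95 and 1.27 in replicates 2 and 3. With replicate 1 set apart, Ptgs2 did not pass over all rows at Post-2hr either (limma adjusted p = 0.0806). Adjusted over the list alone, Ptgs2 was the 1 of 17 prostaglandin genes that passed, at Post-2hr; the list had a median of 0.14 there (adjusted p = 0.0534; with replicate 1 set apart adjusted p = 0.0133, and in that fit adjusted p = 0.158 with an estimated correlation). Setting replicate 1 apart, 2 prostaglandin genes rose at End and 2 at Post-2hr, adjusted over the list alone. Ptger4, a PGE2 receptor, differed by 0.82, 1.08 and 0.72, each ± 0.41, and did not pass. Ptger2 and Ptges differed by at most 0.32. Of the podocyte genes, Nphs1 (nephrin), Wt1 and Podxl differed from Control by between −0.07 and 0.14 at the 3 harvests, with SE of 0.09, 0.10 and 0.51. Axin2 and Ctnnb1 of the Wnt pathway differed by between −0.14 and 0.11.

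Lists that passed at no main comparison are given by their median changes at End, Post-2hr and Post-24hr. These were 0.03, 0.04 and −0.02 for podocyte identity, 0.06, 0.07 and −0.03 for Wnt targets, and 0.04, 0.07 and −0.03 for matrix and TGF-beta targets. Stress and metabolism lists had −0.03, −0.06 and 0.07 (unfolded protein and integrated stress response), −0.05, −0.13 and 0.01 (hypoxia and glycolysis) and 0.02, −0.03 and 0.08 (p53 targets). S phase genes had 0.18, 0.06 and 0.12, circadian clock genes 0.15, −0.03 and 0.04, and mechanosensitive channels −0.01, 0.02 and −0.01. Markers of mesangial cells and pericytes had 0.09, −0.00 and 0.02, and markers of tubule and parietal epithelium −0.03, 0.01 and −0.00. Cytosolic ribosomal proteins had −0.08, −0.05 and 0.02, and histone genes −0.02, −0.01 and −0.11. Setting replicate 1 apart brought 7 further tests past the threshold, each also with replicate number as a block, and none of them with replicate 1 set apart and an estimated correlation. At End these were S phase genes (17 of 17 means higher; adjusted p = 0.00269, and adjusted p = 0.628 with an estimated correlation), NRF2 genes (adjusted p = 0.00307 and 0.274) and actin genes (adjusted p = 0.00888 and 0.519). At Post-2hr they were the prostaglandin list, matrix and TGF-beta targets (adjusted p = 0.0412 and 0.505) and heat shock proteins (adjusted p = 0.0385 and 0.507), and at Post-24hr interferon response genes, which were lower (adjusted p = 0.0434 and 0.572). On replicates 2 and 3 only, S phase and NRF2 genes passed at End and Post-24hr and the prostaglandin list at Post-2hr. The other lists added in that fit were the YAP and TAZ, circadian, hypoxia and tubule lists at End, the last 2 as lower, p53 targets as lower at Post-2hr, and the shear list at Post-24hr. In some tests that did not pass, the camera direction, the median and the mean differed in sign. At End these were podocyte identity, G2 and M phase, p53 and macrophage lists (test down, median and mean above 0) and histones. At Post-2hr they were the mechanosensitive, interferon, sterol, circadian, tubule and histone lists, and at Post-24hr the cAMP, hypoxia, mechanosensitive, mesangial, tubule and ribosomal lists.

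The F test for any difference among the groups called 2 rows, Gpr146 and Plaur, and 7 with replicate 1 set apart; it called 0 without Control replicate 2 or 3 or any Post-2hr array. The sheared and control arrays did not overlap in 7.63% of rows at End, 9.09% at Post-2hr and 5.61% at Post-24hr, where arrays in random order would give 10%. A replicate 1 difference shared by both groups hinders such a separation, so 10% is not the chance share here. Over all rows the log2 changes correlated across genes by 0.484 between End and Post-2hr, where unchanged groups against the same controls gave 0.499 in simulation; genes are not independent replicates. The correlations were 0.329 between End and Post-24hr and 0.393 between Post-2hr and Post-24hr. The covariances of 0.0263, 0.0150 and 0.0192 stood beside simulated values of 0.0373, 0.0374 and 0.0373, or 0.0214, 0.0214 and 0.0213 with the spread left after replicate 1 was set apart. The 3 controls are too few to be divided between the comparisons, and part of any overlap between the comparisons may come from the shared controls.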

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

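The tests of the G2 and M phase pattern and of the immediate early pattern, and the list tests between harvests, were chosen after the results were seen; the counts over other splits of the arrays were planned.

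These results stand out as differences between harvests, tested directly with the controls cancelling. From End to Post-2hr, Plaur changed by 1.02, Vmn1r82 by 1.62, Bmf by −1.67, Gpr146 by −1.19 and Runx1t1 by −0.95, each past the threshold in limma. None of these genes kept its call in all 12 fits that left out 1 array, Runx1t1 kept it in 0, and the Vmn1r82 row was dim. Among lists, the median changes from End to Post-2hr were 0.35 for MAPK feedback regulators, 0.23 for inflammatory genes, 0.17 for cAMP and CREB targets, 0.16 for the shear list, 0.14 for macrophage and leukocyte markers and −0.17 for sterol synthesis. From Post-2hr to Post-24hr the medians were −0.33 for immediate early factors, −0.28 for inflammatory genes, −0.24 for the shear list, −0.23 for cAMP and CREB targets, −0.10 for macrophage and leukocyte markers and 0.58 for G2 and M phase genes. All 12 of these list tests passed with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.525).

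For the 5 comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05. Post-2hr minus Control called 4 rows and the highest other split 0 (1 of the 10 splits gave as many), and Post-2hr minus End called 6 against 0 (1 of 10). End minus Control called 0, with 1 in another split, and Post-24hr minus Control and Post-24hr minus Post-2hr called 0 with 0 elsewhere (10 of 10 each). For gene lists, End called 6 and the highest other split 9 (5 of 10 gave as many), Post-2hr 9 against 16 (3 of 10), and Post-24hr 8 against 13 (5 of 10). The splits with the most lists kept both replicate 1 arrays on 1 side, which points to the set of arrays: such splits called 6 to 9, 7 to 16 and 8 to 13 lists. Among the 6 splits that part the replicate 1 arrays, the other splits reached at most 3, 5 and 3 lists. For the F test, 3 of 100 drawn splits, the real one included, called as many rows as the real 2. This share does not exclude chance, because most of the splits differ from the real one in how they place the replicate 1 arrays. The highest other called 873 and put 3 replicate 1 arrays into 1 group, again a structure of the samples, and 76 of the splits put 2 or more replicate 1 arrays into 1 group, unlike the real one. Of the 24 with 1 such array per group, 1, the real one, called as many, and the others called 0. The F test called 7 with replicate 1 set apart.

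G2 and M phase genes were higher at 24 h in replicates 2 and 3 (all 18 members in each) and in 4 of 18 members in replicate 1. The fit with replicate 1 set apart (adjusted p = 5.9e-10; adjusted p = 0.458 with an estimated correlation) decides nothing about an additive difference between the sets of arrays, since with 1 replicate 1 array in each group it leaves the change itself as it was. A single array as the whole cause is argued against, although the call ended without Control replicate 1, Post-24hr replicate 2 or Post-24hr replicate 3. The replicate 2 and the replicate 3 pairs of arrays, which share no array, had medians of 1.18 and 0.63 at 24 h. No same-numbered pair exceeded 0.32 in size at End or Post-2hr. That bound rests on pairing by number, which is not settled. Against the control mean, these Post-24hr arrays had medians of 1.32 and 1.18, and the highest other array, Post-2hr replicate 3, had 0.71. Time in culture cannot be told apart from shear, because 0 unsheared arrays among the 12 used were labelled with the later time. Shear itself, the difference the design names, stays open, and whether the sets of arrays differed in their change was not tested.

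Immediate early factors were higher than in the controls at all 3 harvests with the preset correlation. With an estimated correlation the list passed at none of them (camera adjusted p = 0.278 at 24 h). A low single control array is argued against, since the median rise at 24 h stayed at 0.33 or more without each control array and the call stayed. The list also passed after median centring (camera adjusted p = 1.26e-08). This decides nothing about a shift of the whole array, since camera compares members with the other genes of the same arrays. Over all rows, the median change at Post-24hr minus Control was 0.002. Low values shared by all control arrays cannot be told apart from a lasting response, because the 12 arrays used hold 0 unsheared ones beyond the shared 3, and such an offset cancels between 2 h and 24 h. A lasting response to shear stays open, as does handling in the flow device, which the design does not separate from shear.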

How the results depend on the processing

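The set-apart fit and the fit on replicates 2 and 3 only were chosen after the data were seen. The numbers do not count as pairing the samples: 17 of 18 same-numbered pairs of arrays deviated together (correlation over 0.1), the lowest being 0.029, although 11 of 12 arrays correlated best with their own number. Pairs of a replicate 2 with a replicate 3 array from different groups also deviated together, 11 of 12 with a correlation over 0.1 (median 0.252). The median was 0.240 for replicate 2 with replicate 2 and 0.277 for replicate 3 with replicate 3. With replicate number as a block, Post-2hr minus Control called 38 rows, Post-2hr minus End 6, Post-24hr minus Post-2hr 5, the F test 1, and 10 lists passed at End; End and Post-24hr against Control called 0 rows. Setting replicate 1 apart gave 36 rows at Post-2hr minus Control, 36 at Post-2hr minus End, 2 at Post-24hr minus Post-2hr and 7 in the F test. Replicates 2 and 3 only, fewer arrays, gave 0 rows for Post-2hr minus Control, 0 for Post-2hr minus End, 0 in the F test, and 11 lists at End. Fits of only the groups compared called 0 rows for Post-2hr minus Control and Post-2hr minus End, with fewer samples to estimate the spread.

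Array weights moved the row counts most, to 77 rows at End, 3863 at Post-2hr and 3 at Post-24hr against Control, 378 for Post-2hr minus End, 20 for Post-24hr minus Post-2hr and 1712 for any difference among the 4 groups, with 3, 4 and 3 lists. Control replicate 2 had a weight of 5.86 and Post-2hr replicate 3 of 5.27 (the rest 0.34 to 1.49), so that fit largely compares those arrays. At Post-2hr minus Control, leaving out rows under the median gave 10 rows, rows with 1 symbol 8 (fewer tests), and no variance moderation 2. The F test called 5 after centring, 7 with either filter on dim rows or rows with 1 symbol, and 4 without moderation. An intensity trend gave 3 rows for Post-2hr minus End. The cause was not tested where none is given. Estimating the correlation for each list, or fry, left 0 lists at each harvest; set apart with an estimated correlation, 1, 4 and 1 passed at End, Post-2hr and Post-24hr.

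Leaving out 1 array gave 1 to 5 rows at Post-2hr minus Control, 0 to 5 at Post-2hr minus End and 0 to 5 in the F test; 0 at End minus Control, Post-24hr minus Control and Post-24hr minus Post-2hr throughout. Post-2hr minus Control called 1 row without Control replicate 2 or 3, End replicate 1 or Post-2hr replicate 2, and 2 without Post-2hr replicate 1 or 3 or Post-24hr replicate 3; Post-2hr minus End called 0 without End replicate 1 or 3 or Post-2hr replicate 3. List counts ran from 4 to 10, 6 to 12 and 5 to 10. The lists that passed in all 12 such fits were immediate early factors at the 3 harvests, MAPK feedback at Post-2hr and Post-24hr, and the shear, inflammatory and macrophage lists at Post-2hr. Leaving out 1 array also unbalances the sets of arrays, so these values mix the array with the replicate 1 difference. Where a fit left 2 arrays in a group, their spread was pooled with the other groups. Over all settings, 1476 values of named genes stayed on their side of the threshold, 68 passed newly and 90 no longer passed; for list tests these were 1955, 87 and 130, and none passed with the other sign. Signal over background is not known here, so dim rows such as Vmn1r82 are the least certain.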

Other observations

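The tests of another cell type and of a slower cycling state were chosen after the results were seen; the other picks of arrays and the quantile normalization test were set before theirs were seen.

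Several clock and stress genes moved within lists that did not pass as wholes. At Post-2hr, adjusted over the list alone, Bhlhe40, a repressor of clock genes, rose by 1.33 ± 0.41 and Arntl, a core clock activator, by 0.70 ± 0.24, while Dbp (−0.78 ± 0.21) and Per3 (−0.48 ± 0.12), clock output and feedback genes, fell; over all rows none of these 4 passed. At End, Bhlhe40 (1.37 ± 0.41) and its relative Bhlhe41 (0.40 ± 0.11) rose, adjusted over the list alone, as did the heat shock cochaperone Dnajb1 (0.51 ± 0.13). Among p53 targets, Plk2 rose at Post-2hr (0.66 ± 0.10) and Post-24hr (0.62 ± 0.10), and Sesn1 fell at Post-2hr by 0.88, adjusted over the list alone. Of the actin and adhesion genes, the integrin subunit Itga5 (0.57 ± 0.13) and Pdlim7 (0.33 ± 0.08) rose at Post-2hr, adjusted over the list alone.

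The replicate 1 arrays carried a profile of their own, in genes named here after their values were seen. Higher in replicate 1 were Car6, a secreted carbonic anhydrase (4.77 ± 0.12, SE), Cdsn, a protein of epidermal junctions (4.33 ± 0.08) the integrated stress response genes Trib3 (2.74 ± 0.10) and Ddit3 (2.58 ± 0.09), and the cystine transporter Slc7a11 (2.66 ± 0.15). Lower were the chemokine Ccl17 (−3.71 ± 0.15), Mycn (−3.22 ± 0.17) and Nppa (−3.17 ± 0.14). Interferon response genes were lower by a median of −0.74 and the NRF2 list was higher by 0.36, each with an adjusted p = 0.198 with an estimated correlation.

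Of 81 picks of 1 array per group, 1, the replicate 1 arrays, called 7112 rows, and the highest other pick called 6. These arrays were singled out from the same values, so this rank does not by itself exclude chance. Array scaling stays open. A share of 0.863 of the 7112 rows still passed after quantile normalization, but RMA already includes that step, so its repeat is a weak test. Cells of another type stay open: the largest median difference over 4 marker lists was 0.26 in size, but members went both ways (Cd68 2.20, Cd14 0.51, Csf1r −1.43 and Aqp1 −1.42), and other cell types were not tested. A slower cycling state of the replicate 1 cultures stays open: both cell cycle lists were lowest in replicate 1 in 4 of 4 groups, but this restates the difference, and no independent value tests it. A batch of arrays or RNA extractions could give such a difference too, and the labels name no batch to test.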
